A study of Mus musculus with 8 samples.

How the data were processed

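RNA of mouse embryonic fibroblasts (strain C57BL/6) was sequenced as 8 libraries in 4 groups of 2, Illumina mRNA sequencing per the labels. Per the submitters' processing notes, reads were processed with CASAVA 1.8, TopHat, Cufflinks and Cuffdiff on mm9. Versions of TopHat, Cufflinks and Cuffdiff, masking and normalization options are not stated. The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to library size) for 30028 RefSeq transcripts of 23235 symbols in each library. It also holds the authors' group means and, for 3 comparisons, the authors' Cuffdiff p-values and q-values, which are quoted only as theirs. The deposited table also lists the length of each transcript in bases, per the file headers. Transcript accessions were matched to symbols with a table of the GRCm38 assembly, which was used for names only. Of the transcripts, 28875 (96.2%) matched, and 47 with symbols changed to dates were restored. All coordinates are mm9, counted from 1.

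FPKM of transcripts of a gene were summed, separately for each chromosome. In 12350 genes with a single transcript of at least 1000 bases, low FPKM values were whole multiples of what 1 fragment is worth once 204.1 bases were taken from the length, within a tolerance of 0.05 fragments, for 100% of the low values in each library. This gave each library's implied total, and the fragments used for the chi-square of each pair. The same fragments, divided by the number of possible read starts on both strands, gave the share of positions in use. That share was over 50% in 473 and over 20% in 3943 of the tested genes of at least 1000 bases. Whether depth and a limit of 1 read per position shift the FPKM of such genes was left open. Gapdh was listed between 0.0682 and 0.599 FPKM and Actg1 between 1.35 and 1.68, so low listed values need not mean low transcript levels.

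The test planned before the data were examined was limma-trend on log2(FPKM + 1) over all 8 libraries, on genes with at least 1 FPKM in at least 2 libraries. It was changed in 2 ways after the data were seen. First, since the control pair and the knockout pair each differed by less than sampling noise, each pair was averaged and counted once. The fit therefore had 6 samples, 2 residual degrees of freedom and 2.15 prior degrees of freedom, and the spread came from the rescue clones alone. Second, genes whose longest transcript is under 300 bases (184 of 12209) were left out, because their FPKM hang on few fragments. This left 12025 genes. The fit as planned is given among the alternatives. All groups were fitted together without covariates, the 5 comparisons were tested two-sided, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05.

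On simulated data with the fitted spread, 100 genes changed by 3 on the log2 scale and 100 by 1 among 12025. For TAFH-deleted against wild-type rescue 84 and 15 were recovered with 4 unchanged genes called, for wild-type rescue against knockout 78 and 10 with 1 unchanged gene called, and for knockout against control 48 and 2 with 3 unchanged genes called. With 1000 genes changed by each amount between the rescue forms, 961 and 641 were recovered with 70 unchanged genes called, so recovery depended on how many genes change. All samples of a simulated gene had the same spread. In the data, log2 differences between clones had an SD of 0.203 for wild-type and 0.575 for TAFH-deleted rescue. The simulated counts need not hold for such unequal spreads.

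Gene lists were fixed before the data were examined, and 27 of 32 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 135 tests (27 lists in 5 comparisons). With an estimated correlation, camera rests on the 2 residual degrees of freedom, so almost no list could pass after adjustment. Camera p-values at the preset correlation are given only for TAFH-deleted against wild-type rescue, which has 2 samples on each side. For knockout against control, and for Wnt response genes in wild-type rescue against control, a list's median is placed among 10000 random lists matched on mean expression in 20 bins. List medians of the remaining comparisons are given without a test. Genes were named by a rule fixed before the data were examined: per comparison the 8 largest rises and falls among called genes with groups that do not overlap and a group mean of at least 5 FPKM, leaving out predicted and small RNA genes. Where none were called, the 4 largest each way were given as values, and in lists with a call up to 4 members with the smallest adjusted p. The genes at least 2-fold lower in knockout, other list members named in comparisons without calls, and the Y-linked genes were chosen after their values were seen. Genes of moderate level, used for chromosomes, had a mean log2(FPKM + 1) of at least that of 2 FPKM and under 20% of positions in use. Unchanged groups sharing the knockout sample were simulated 100 times, with the spread of the rescue clones for every sample.

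Alternatives were pseudocount 0.1, no filter, a mean of at least 5 FPKM, quantile and median scaling, robust eBayes, fits on the groups compared alone, a replicate block, each library left out, a threshold of 0.1, and a log2 change of at least 1. Added after the data were seen were all 8 libraries as separate samples with and without the block, genes without X and Y, chromosome centring, a correction for filled positions, genes under 20% filled, and short transcripts kept. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.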

Results

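RNA sequencing was used to measure transcript levels in mouse embryonic fibroblasts, connective tissue cells grown in culture, that carry or lack Taf4, a subunit of the general transcription factor TFIID. The 8 libraries fall into 4 groups of 2. Control cells carry 1 floxed and 1 null Taf4 allele, although another label field calls them wild type, and knockout cells carry none that is intact according to the labels. The other groups are clones of knockout cells that received human TAF4, either full length (wild-type rescue, clones 1 and 2) or lacking its TAFH domain (TAFH-deleted rescue, clones 1 and 2). The TAFH domain is a conserved part of TAF4, and the series title ties TAF4 to E proteins, the basic helix-loop-helix transcription factors encoded by Tcf3, Tcf4 and Tcf12. The authors deposited FPKM (fragments per kilobase of transcript, scaled to library size) for 30028 RefSeq transcripts on the mm9 genome. The FPKM steps between low values imply totals, in units of 1e6 fragments, of 17.3 in each control library and 14.8 in each knockout library. They imply 17.1 and 16.9 in the wild-type rescue clones, and 14.3 and 16.2 in the TAFH-deleted clones. For a transcript of 2 kilobases, 1 fragment was worth between 0.0322 and 0.0390 FPKM.

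The control libraries differed from each other by less than the sampling noise, and so did the knockout libraries. Over genes with 2 to 7 fragments, the chi-square per gene, which is 1 for independent reads, was 0.721 ± 0.0305 (SE) in the control pair and 0.567 ± 0.0283 (SE) in the knockout pair. It was 1.27 ± 0.0401 (SE) between the wild-type rescue clones and 1.76 ± 0.0543 (SE) between the TAFH-deleted clones. The control pair and the knockout pair were therefore each averaged and counted as 1 sample, which leaves 6 samples. Values of these groups carry no replicate error, and differences against them have no replicate check of their own. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these samples. Abundant transcripts came close to a limit of 1 read per position: in every library the most fully covered gene had between 92.7% and 97.4% of its possible read starts (each base on each strand) in use. The test covered 12025 genes, and differences are given on the log2(FPKM + 1) scale, which understates changes of low genes.

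Taf4a, the mouse Taf4 gene, did not separate the libraries labelled knockout from the control. Its transcript (chromosome 2) was at 11.3 FPKM in control and 12.5 FPKM in the libraries labelled knockout. It was at 14.5 and 15.0 FPKM in the wild-type rescue clones and at 14.7 and 19.2 FPKM in the TAFH-deleted clones. The labels do not say which exons were deleted, and reads of the human transgene may align to the mouse gene, so this level does not check the labels. The paralog Taf4b was at 2.47 FPKM in control, 2.03 in knockout, 1.82 and 2.07 in the wild-type rescue clones, and 1.64 and 6.13 in the TAFH-deleted clones. Of the E-protein genes, Tcf3 was at 60.2 FPKM in control and 52.7 in knockout, Tcf4 at 45.1 and 34.6, and Tcf12 at 45 and 51.6. Id1, which encodes an inhibitor of E proteins, was at 80.1 FPKM in control and 106 in knockout, Id2 at 47.5 and 50, Id3 at 108 and 133, and Id4 at 1.79 and 0.904. For a transcript of 2 kilobases, 1 read per position corresponds to 129 FPKM in control and 150 in knockout. Rises of abundant genes such as Id1 and Id3 may therefore reflect that limit. None of the 17 measured TFIID genes and none of the E-protein and Id genes passed the test in any of the 5 comparisons. Only TAFH-deleted against wild-type rescue called any gene at all. In the other comparisons, not passing therefore does not show that these genes stayed unchanged.

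The comparison of knockout with control asks what loss of Taf4 changes. More genes were lower than higher in the knockout sample: 693 genes were at least 2-fold lower and 96 at least 2-fold higher. The largest drops included Stmn2, a microtubule regulator of neurons, at 56.8 FPKM in control and 0.0993 in knockout, and Npnt, an extracellular matrix protein that binds integrins, at 41.2 and 0.244. Fmod, a collagen-binding proteoglycan, was at 50.1 and 1.02 FPKM, and S1pr3, a receptor for sphingosine 1-phosphate, at 24.3 and 0.300. The largest gains were Cpxm2 at 0.140 FPKM in control and 9.29 in knockout, Slc16a3, a lactate exporter, at 2.20 and 19.5, and Ifi27l2a, an interferon-induced gene, at 1.23 and 12.9. Amd1 was at 0.00214 and 6.95 FPKM but also differed between clones of the same rescue group, at 5.48 and 0.00218 in the wild-type clones. The TAFH-deleted clones differed at least 2-fold from each other in 923 genes.

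Gene lists fixed in advance placed these differences. The largest median was that of neural and glial markers, which include Stmn2: it was -1.17, with 5 of 5 lower, 3 of them at least 2-fold, at percentile 0.37 of 10000 random lists matched on mean expression. Cartilage and bone markers had a median of -0.53, with 6 of 8 lower, at percentile 0.99. Of 14 measured Wnt response genes, 11 were lower in knockout, with a median log2 difference of -0.73 that lay below all of the matched lists. Sfrp1, a secreted Wnt antagonist, was at 50.3 FPKM in control and 15.7 in knockout, and Tcf7 at 3.19 and 0.284. Of 37 extracellular matrix genes, 21 were lower and 16 higher, with a median of -0.15, and 9 were at least 2-fold lower and 0 at least 2-fold higher. Dcn, which encodes decorin, was at 24.2 and 0.642 FPKM, and Mfap5, a microfibril protein, at 47.3 and 3.81. Of 36 cell cycle genes, 30 were lower, with a median of -0.33. Interferon-stimulated genes lay the other way: 26 of 29 were higher in knockout, with a median of 0.66, and Usp18 was at 5.26 and 24.6 FPKM. Glycolysis and hypoxia genes had a median of 0.36, with 21 of 23 higher, and Ldha was at 61.5 and 79.1 FPKM. Chemokine and NF-kB target genes had a median of 0.35, with 21 of 24 higher, and the chemokine gene Ccl20 was at 13.1 and 67.7 FPKM. Against knockout, the interferon list stood at -0.27 and -1.07, the chemokine list at -0.10 and -1.34 and the cell cycle list at 0.12 and 0.66 in the 2 TAFH-deleted clones. In these lists clones of the same form lay further apart than knockout and control. This was not so in the Wnt and glycolysis lists. The medians of the interferon, glycolysis and chemokine lists lay above all 10000 matched random lists, and those of the extracellular matrix and cell cycle lists below all of them. Random lists ignore that members of a list move together, and camera with an estimated correlation called none of these 5 lists or the Wnt list here (adjusted p = 0.674 for interferon, glycolysis and Wnt, 0.699 for extracellular matrix, and 0.767 for chemokine and cell cycle). With 2 residual degrees of freedom that camera test had little power, so it does not decide whether these lists moved. The 14 E-protein targets known from other cells stood at a median of -0.06, at percentile 62.0 of matched lists, and at 0.15 under quantile normalization. Of these targets 7 were lower and 7 higher, with 5 at least 2-fold lower and 0 at least 2-fold higher.

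**Figure D1:**
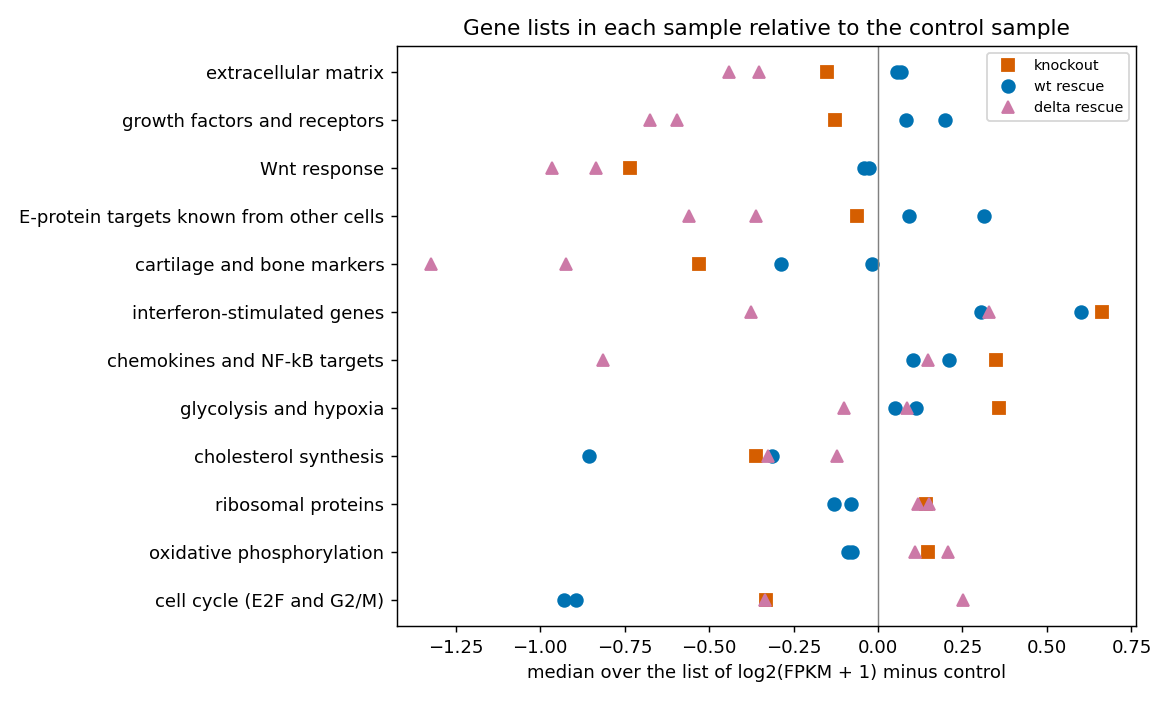
Median over each gene list (vertical axis) of log2(FPKM + 1) minus the control sample (horizontal axis), with a square for the knockout sample, circles for the 2 wild-type rescue clones and triangles for the 2 TAFH-deleted clones. Wnt response genes sit at -0.73 in knockout, at -0.04 and -0.03 in the wild-type rescue clones and at -0.83 and -0.96 in the TAFH-deleted clones.

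No gene passed the limma test at an adjusted p of 0.05 in knockout against control, where each side is a lone sample assumed to vary like the rescue clones. An unadjusted p under 0.05 was reached by 1108 genes, against 601 by chance alone. The 0 changed with several choices. Without clone 1 of the TAFH-deleted form, which is not in this comparison, 995 genes were higher and 1717 lower, and without clone 2 of that form 1001 and 1660. With both kept, 36 were higher and 177 lower without a filter on low values, and 1088 and 1676 in the fit as planned, which counts each library of a pair and keeps short transcripts. The authors' deposited table, from Cuffdiff with options that are not stated, calls 7557 of 14051 transcripts, 3183 higher and 4374 lower. The balance of sizes depended on scaling: 12.2% of the genes that differed at least 2-fold were higher in knockout as deposited, and 37.9% after quantile normalization.

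The comparison of wild-type rescue with knockout asks which genes full-length human TAF4 moves. Genes at least 2-fold higher than in knockout numbered 343, and 132 were at least 2-fold lower. The largest gains were Vsig1, an immunoglobulin-family surface protein, at 0.0566 FPKM in knockout and 28.6 ± 0.228 (SD, n = 2) in the wild-type rescue clones, Npnt at 0.244 and 24.1 ± 1.62, Fmod at 1.02 and 28.2 ± 2.82, and Col8a2, a short-chain collagen, at 0.434 and 16.9 ± 2.84. The largest drops were Bhlhb9, an X-linked gene, at 10.2 FPKM in knockout and 0.0339 ± 0.0162 in the rescue clones, Slc16a3 at 19.5 and 1.24 ± 0.576, and Pir, also X-linked, at 8.46 in knockout and at 0 and 0.0847 in the clones. Cpxm2 was at 9.29 and 0.266 ± 0.25 FPKM. Of the 14 Wnt response genes, 10 were higher, with a median of 0.61, and of 26 growth factor and receptor genes, 20 were higher, with a median of 0.33. Hgf, hepatocyte growth factor, was at 0.265 FPKM in knockout and 10.2 ± 2.41 in the clones, and Pdgfra, a platelet-derived growth factor receptor, at 17.3 and 54.8 ± 2.70. Cell cycle genes were lower in 33 of 36, with a median of -0.52. The limma test called 0 genes, with 1602 at an unadjusted p under 0.05. Fitted without the other groups it called 1338 higher and 1831 lower, and without TAFH-deleted clone 1 it called 1310 and 1901, so the 0 depended on clones outside this comparison. The authors' deposited table calls 3639 of 14106 transcripts, 1983 higher and 1656 lower.

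The comparison of TAFH-deleted rescue with knockout asks what TAF4 without that domain moves. Here 86 genes were at least 2-fold higher and 353 at least 2-fold lower than in knockout. Taken alone, clone 1 had 50 and 264 such genes, and clone 2 had 423 and 594. All 24 chemokine and NF-kB target genes were lower, but by unequal amounts: the median was -0.10 in clone 1 and -1.34 in clone 2. Saa3, an acute-phase protein, was at 143 FPKM in knockout and at 33.0 and 1.32 in the clones. Ccl20 was at 67.7 FPKM in knockout and at 13.7 and 0.414 in the clones. Nos2, inducible nitric oxide synthase, was at 16.3 in knockout and at 0.963 and 0 in the clones, and Orm2 at 24.9 and at 3.44 and 0.108. The largest gains were mostly those of clone 2: Lipg was at 3.18 FPKM in knockout and at 4.13 and 47.6 in the clones, Ngef at 0.278 and at 1.36 and 18, Ramp3 at 0.199 and at 0.551 and 11.9, and Prkg2 at 1.5 and at 5.29 and 17.6. Every one of the 36 cell cycle genes was higher than in knockout, with medians of 0.12 in clone 1 and 0.66 in clone 2. The limma test called 0 genes, with 789 at an unadjusted p under 0.05. It called 2136 higher and 1877 lower without clone 1, and 119 and 339 without clone 2, where a lone TAFH-deleted clone is left. The authors' deposited table calls 135 of 14104 transcripts, 39 higher and 96 lower.

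The direct comparison of the TAFH-deleted with the wild-type rescue clones, 2 against 2, asks how clones of the 2 forms differ. It gave the only calls: 112 genes were higher and 203 lower in TAFH-deleted clones at an adjusted p of 0.05 (limma, Benjamini-Hochberg). The wild-type clones differed at least 2-fold from each other in 39 genes, and the TAFH-deleted clones in 923. Whether clones of a form arose independently is not stated, so form and clone origin cannot be told apart. Vsig1 (chromosome X, 137442147 to 137474011, mm9) was at 28.6 ± 0.228 FPKM (SD, n = 2) with wild-type TAF4 and 0.0554 ± 0.00871 with the deleted form, a log2 difference of -4.81 ± 0.17 (SE, adjusted p = 0.0204). Lama4, a laminin chain of basement membranes (chromosome 10, 38685321 to 38829994), was at 25.8 ± 1.85 and 0.180 ± 0.000522 FPKM, and Ctsk, the collagen-cleaving protease cathepsin K (chromosome 3, 95303208 to 95313284), at 26.5 ± 0.180 and 0.464 ± 0.0423. Rspo3, a secreted activator of Wnt signalling, was at 48.7 ± 8.65 and 1.43 ± 1.27, Vit at 27.3 ± 2.20 and 0.410 ± 0.189, Plxdc2 at 43.6 ± 4.49 and 2.42 ± 1.63, and Col8a2 at 16.9 ± 2.84 and 0.322 ± 0.0968. Dcn was at 19.1 and 11.6 FPKM in the wild-type clones and listed at 0 and 0.0387 in the TAFH-deleted clones.

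The largest rises were Bhlhb9 (chromosome X, 132420390 to 132425620) at 0.0339 ± 0.0162 FPKM with wild-type TAF4 and 18.2 ± 0.491 with the deleted form, a log2 difference of 4.21 ± 0.17 (SE, adjusted p = 0.0204), and Pir at 0 and 0.0847 in the wild-type clones and 11.9 and 11.4 in the others. Nkx2-5, a homeobox gene of the heart (chromosome 17), was at 0.489 ± 0.438 and 9.77 ± 2.40 FPKM, Panx1, a channel protein, at 0.330 ± 0.198 and 6.95 ± 1.40, and Cd302 at 1.87 ± 0.0268 and 12.4 ± 2.37. Hmgb3 was at 0.628 ± 0.196 and 5.67 ± 0.453, Gkap1 at 3.86 ± 0.976 and 18.5 ± 1.87, and Slc43a3 at 0.625 ± 0.360 and 5.12 ± 0.487. Of the 112 genes called higher, 53 lie on the X chromosome, which holds 381 of the 12025 genes tested, while 7 of the 203 called lower do. The 228 X genes of moderate level had a median log2 difference of 0.71 between the forms.

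**Figure D2:**
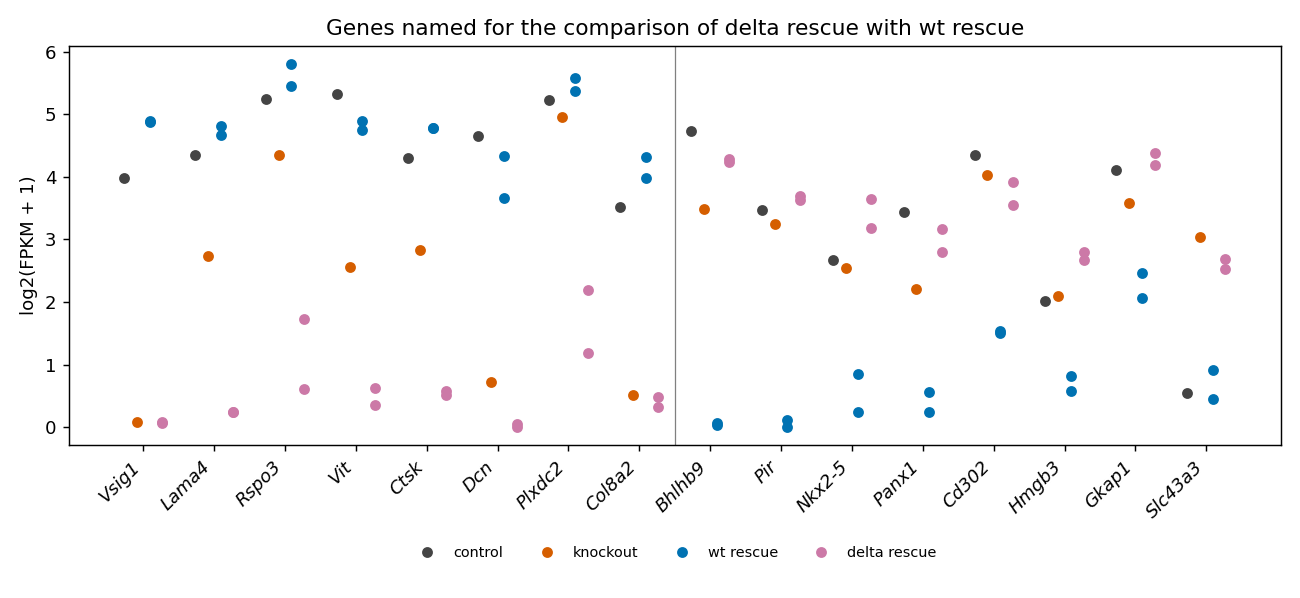
log2(FPKM + 1) of the 16 genes named for TAFH-deleted against wild-type rescue (horizontal axis), with a point for the control sample, a point for the knockout sample and a point for each of the 2 clones of each rescue. The genes left of the line were lower in both TAFH-deleted clones, such as Lama4 at 0.180 FPKM against 25.8, and those right of it were higher.

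Several fixed lists moved with these genes. All 36 measured cell cycle genes were higher with the deleted form, 4 of them called over all genes and 17 adjusted over the list alone, with a median log2 difference of 0.78, or 0.60 for clone 1 and 1.17 for clone 2 (camera adjusted p = 1.4e-08, but adjusted p = 0.674 with an estimated correlation). The mitotic genes Birc5 and Bub1 were at 23.5 ± 0.0342 and 11.1 ± 0.677 FPKM in the wild-type clones and at 56.1 ± 5.85 and 26.7 ± 1.83 in the TAFH-deleted clones, Ccna2, cyclin A2, at 26.9 ± 0.331 and 58.9 ± 5.4, and Kif11, a spindle motor, at 9.33 ± 0.668 and 24.5 ± 3.93. Among extracellular matrix genes, 30 of 37 were lower, 3 of them called (Lama4, Dcn and Col12a1) and 11 adjusted over the list alone (camera adjusted p = 8.8e-07, but adjusted p = 0.674 with an estimated correlation). Growth factor and receptor genes were lower in 24 of 26, with 3 called: Hgf at 10.2 ± 2.41 against 0.132 ± 0.0848 FPKM, Pdgfra at 54.8 ± 2.70 against 10.1 ± 1.88, and Igfbp4 at 93.2 ± 3.28 against 37.1 ± 1.64. In that list 11 genes were lower adjusted over the list alone (camera adjusted p = 8.4e-07, but adjusted p = 0.674 with an estimated correlation). Of the Wnt response genes, 10 of 14 were lower, with 3 called and 6 adjusted over the list alone (camera adjusted p = 0.0014, but adjusted p = 0.674 with an estimated correlation). Their median was -0.71, with -0.21 for clone 1 and -0.76 for clone 2 against the mean of the wild-type clones. Those called were Sfrp1 at 62.2 ± 5.35 against 6.92 ± 1.68 FPKM, Fzd7, a Wnt receptor, at 44.7 ± 1.68 against 22 ± 1.37, and Wisp2. E-protein targets known from other cells were lower in 11 of 14, with a median of -0.64, 0 called over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00045, but adjusted p = 0.674 with an estimated correlation). The epidermal gene Cdsn was at 60.1 ± 0.433 and 18.9 ± 5.74 FPKM and had an adjusted p of 0.0518.

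Oxidative phosphorylation genes were higher in 31 of 31, with 1 called over all genes, Ndufa9, and 17 adjusted over the list alone (camera adjusted p = 2.1e-07, but adjusted p = 0.674 with an estimated correlation). Ribosomal protein genes were higher in 44 of 49 with 0 called, and 0 adjusted over the list alone (camera adjusted p = 0.00012, but adjusted p = 0.674 with an estimated correlation). The oxidative phosphorylation and ribosomal lists also stood at 0.15 and 0.14 in knockout against control. Apart from control, the deepest library, the medians of both lists fell as implied library totals rose. Depth and form were therefore not told apart for them. TFIID subunit genes were higher in 15 of 17 with 0 called, and 0 adjusted over the list alone (camera adjusted p = 0.0228, but adjusted p = 0.674 with an estimated correlation), and their median of 0.31 fell to 0.15 with each chromosome centred on its median. Cartilage and bone markers had the largest median of any list, -1.01, and were lower in 7 of 8 (camera adjusted p = 0.00578, but adjusted p = 0.674 with an estimated correlation), and Col2a1, a cartilage collagen, was called. Also lower in most members, each with an adjusted p of 0.674 to 0.767 with an estimated correlation, were retinoic acid response genes (9 of 11, camera adjusted p = 0.00382), immediate early and CREB targets (17 of 20, camera adjusted p = 0.00345), SRF targets (12 of 15, camera adjusted p = 0.0429) and TGF-beta response genes (16 of 24, camera adjusted p = 0.0482, 2 called). Chemokine and NF-kB targets were lower in 22 of 24 (camera adjusted p = 0.00431) and interferon-stimulated genes in 23 of 29 (camera adjusted p = 0.0111), with adjusted p = 0.767 and 0.777 with an estimated correlation, but clone 1 stood at medians of 0.00 and 0.10 and clone 2 at -1.05 and -0.69. Cholesterol synthesis genes were higher in 20 of 22, with a median of 0.48 and 1 called (camera adjusted p = 0.0109, but adjusted p = 0.767 with an estimated correlation). Against control this list stood at -0.86 and -0.31 in the wild-type clones and at -0.33 and -0.12 in the TAFH-deleted clones. Wild-type clone 2 thus lay close to TAFH-deleted clone 1. In all, 16 of the 27 lists passed with the preset correlation of 0.01 in this comparison. None of them held with an estimated correlation, where their adjusted p ran from 0.674 to 0.777. With 2 residual degrees of freedom that test could pass almost no list, so it does not decide which lists moved. E-protein targets, with an estimated correlation of -0.041, also stood at 0.674 there. The estimated correlation was 0.593 for cell cycle genes and 0.632 for SRF targets, far above the preset 0.01. Camera p-values of these lists at the preset correlation may therefore be much too small.

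The counts of 112 and 203 hung on single libraries and on the filter. With either wild-type clone left out limma called 0 genes, without TAFH-deleted clone 1 it called 3854 higher and 2868 lower, without clone 2 it called 2807 and 1999, and without a filter on low values it called 0. With all samples, 3465 genes reached an unadjusted p under 0.05. With all 8 libraries as separate samples, the test as planned apart from the length limit, 2718 genes were higher and 1848 lower, so that 59.5% of the calls were higher. The exclusion of transcripts under 300 bases, chosen after the data were seen, raised the calls from 24 higher and 82 lower, and without genes on X and Y 9 were higher and 81 lower. Under median scaling 44 genes were higher and 160 lower, 21.6% higher against 35.6% as deposited, and with each chromosome centred on its median 17 were higher and 136 lower, 11.1% higher.

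A further question is whether genes lowered in the knockout depend on the TAFH domain. The contrasts of knockout with control and of TAFH-deleted with wild-type rescue share no library. Of the 203 genes called lower with the deleted form, 89 were also at least 2-fold lower in knockout than control, against 11.7 for independent lists. Outside X, 83 of 196 genes called lower were in this overlap. Other settings changed how many genes were called. The overlap by size of knockout-lowered genes was 0 without a filter, where 0 genes were called lower. It was 21 of 46 called lower at a mean of at least 5 FPKM, 43 of 82 with short transcripts kept and 47 of 81 refitted without X and Y. It ran from 0, without either wild-type clone, to 312, without TAFH-deleted clone 2. The 89 genes include Vsig1, Lama4, Vit, Ctsk, Dcn, Col8a2, Tmem159 and Npnt, the 8 with the largest falls between the forms. They were picked by size in the knockout, since no gene was called there. Vit was at 39.3 FPKM in control, 4.92 in knockout, 27.3 ± 2.20 in wild-type rescue and 0.410 ± 0.189 in TAFH-deleted rescue. Of the 112 genes called higher, 6 were at least 2-fold lower in knockout, against 6.45 for independent lists. Slc43a3 was the single gene called higher that was also at least 2-fold higher in knockout, at 0.459 FPKM in control and 7.20 in knockout. Over all 693 genes that were at least 2-fold lower in knockout, the median log2 difference between the forms was -0.30, against -0.15 to -0.06 for the central 95% of matched random lists, and it was -0.48 for clone 1 and -0.17 for clone 2. Its size depended on the pseudocount and was larger with a pseudocount of 0.1. The median alone was not particular to lowered genes, since the 96 genes at least 2-fold higher in knockout had a median of -0.29, with 0.12 for clone 1 and -0.56 for clone 2. Across genes, which are not independent replicates, the difference between the forms correlated with the knockout difference at r = 0.17 (Spearman rho = 0.05). The r was 0.35 with clone 1 and 0.01 with clone 2.

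The same 693 genes were read in each rescue against knockout. At least 2-fold higher levels than in knockout were reached in both wild-type clones by 207 of them (29.9%) and in both TAFH-deleted clones by 14 (2.02%), while among all tested genes the shares were 2.37% and 0.158%. Of the 96 genes at least 2-fold higher in knockout, 22 (22.9%) were at least 2-fold lower than knockout in both wild-type clones and 32 (33.3%) in both TAFH-deleted clones, with medians of -0.79 and -1.21. For the lowered genes, independent lists would share 16.4 and 1.09 genes. These comparisons share the knockout sample, so part of the excess may come from its chance values. The median log2 difference to knockout was 0.52 with wild-type TAF4 and 0.13 with the deleted form in the lowered genes. In simulated groups without any effect, genes picked the same way had medians of 0.68 and 0.67, but only 111 genes were picked on average. The simulation gave every sample the spread of the rescue clones, since control and knockout carry no replicate error. Its values are therefore no measured chance level for the knockout sample. The covariance of the knockout difference with the rescue difference was -0.13 for wild-type rescue, against -0.06 simulated, and -0.07 for TAFH-deleted rescue, against -0.06 simulated.

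The comparison of wild-type rescue with control shows how far the rescued clones stood from cells that kept Taf4. At least 2-fold lower levels were found for 557 genes and at least 2-fold higher levels for 20 as deposited. After quantile normalization the counts were 473 lower and 118 higher. Stmn2 was at 56.8 FPKM in control and 0.0863 ± 0.0729 in the clones, Gas6, a ligand of TAM receptors, at 46.5 and 0.652 ± 0.152, Perp at 38.5 and 0.606 ± 0.413, and Bhlhb9 at 25.5 and 0.0339 ± 0.0162. Higher levels were found for Ifitm1 at 4.40 and 16.8 ± 5.70 FPKM, Syt5 at 4.01 and 11.4 ± 0.319, S100a8 at 13.2 and 32.9 ± 5.09, and Hist2h3c1 at 5.25 and 13.7 ± 1.86. All 36 cell cycle genes were lower, with a median of -0.90, and the Wnt response genes were at a median of -0.07, at percentile 35.3 of matched lists. The limma test called 0 genes, with 1340 at an unadjusted p under 0.05. Fitted without the other groups it called 759 higher and 2095 lower, and without TAFH-deleted clone 1 it called 755 and 2198.

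Chromosomes differed as units. On X, 228 genes of moderate level had a median log2 difference to knockout of -0.59 and -0.57 in the wild-type rescue clones and 0.14 and 0.15 in the TAFH-deleted clones, while the autosomes spanned -0.15 to 0.33 in wild-type clone 1. The Y-linked gene Uty was at 15.8 FPKM in control, 14.7 in knockout, 24.9 and 27.5 in the wild-type rescue clones and 17.6 and 14.8 in the TAFH-deleted clones. Chromosome 1 stood at 0.33 and 0.34 in the wild-type rescue clones and at -0.26 in knockout against control.

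**Figure D3:**
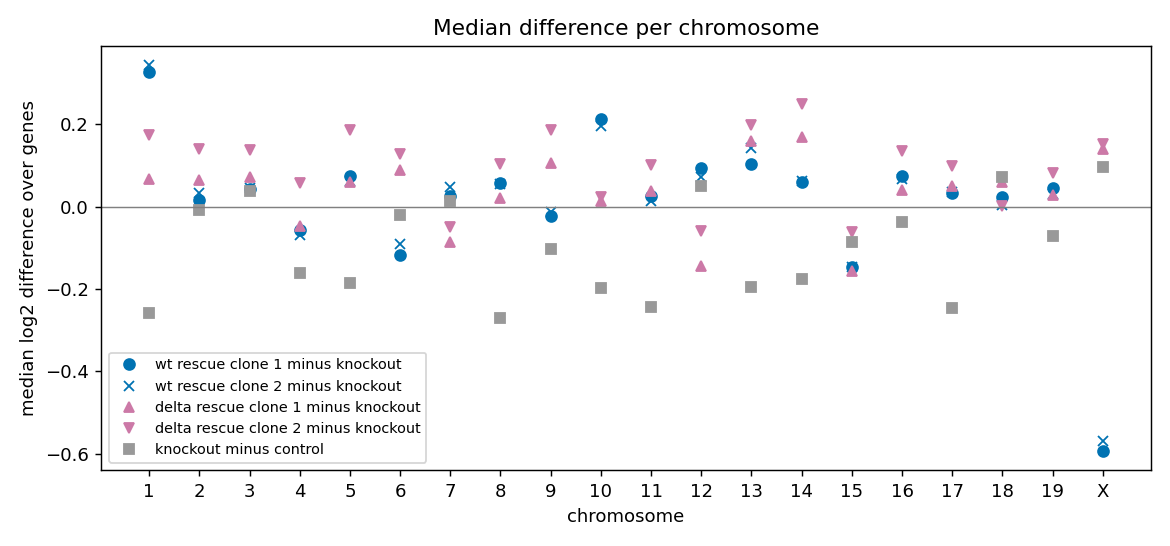
Median log2 difference over genes of moderate level (vertical axis) per chromosome (horizontal axis), for each rescue clone minus knockout and for knockout minus control. X stands apart at -0.59 and -0.57 in the 2 wild-type rescue clones.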

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

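Between the rescue forms, 112 genes were higher and 203 lower with the TAFH-deleted form. The chromosome and list medians below stood out because both clones of one form lay above knockout and both of the other below it, a rule that uses no test. The chromosome differences were not tested. For chromosomes the medians between the forms were 0.22 for 6, -0.10 for 7, 0.13 for 9, -0.21 for 12 and 0.71 for X, and no technical explanation was tested for those other than X. The list medians were 0.31 for TFIID subunits, -0.64 for E-protein targets, -0.16 for TGF-beta response, -0.42 for extracellular matrix, 0.78 for cell cycle, -0.39 for retinoic acid response, -0.71 for Wnt response, -0.60 for growth factors and receptors, 0.20 for histone and chromatin remodelling, -0.26 for adipocyte markers and -1.01 for cartilage and bone markers. Camera tested these lists between the forms: 9 of the 11 passed at the preset correlation, all but histone and chromatin remodelling and adipocyte markers. With an estimated correlation, where almost no list could pass, 0 passed. The clones differed, at 0.60 and 1.17 for cell cycle and 0.07 and 0.36 for histone and chromatin remodelling. Each of these list medians kept its sign under quantile and median scaling, with chromosomes centred, and when corrected for filled positions, where cell cycle ran from 0.73 to 0.84. TFIID subunits fell to 0.15 with chromosomes centred, and adipocyte markers moved to -0.13 after quantile normalization.

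All tests of the small differences within the control pair and the knockout pair were chosen after seeing the result. Reads shared between the libraries of a pair could explain a chi-square per gene of 0.567 in the knockout pair, below the 1 of independent reads. The limit of 1 read per position does not explain it, since genes with 2 to 7 fragments, far from that limit, gave 0.721 in the control pair. How the pairs were made is not stated and stays open.

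All tests of the lower level of X genes in both wild-type rescue clones, which with a median of 0.71 between the forms also enters the genes called higher, were chosen after seeing the result. A lower copy number of the whole X chromosome is consistent with all windows of 40 Mb lying low, the highest at -0.51. Depth or expression level does not explain it, since the X median lay at percentile 0 of matched autosomal lists. A response of a few X genes does not explain it either, since 73.7% of X genes lay below all other samples in both clones. Regulation of the whole chromosome by full-length TAF4 and the origin of the clones were not tested, and no DNA was measured.

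All tests of the higher level, in knockout than control, of genes with over 50% of positions in use were chosen after seeing the result. Depth together with a limit of 1 read per position may explain it, because such genes were also higher, by 0.10, in the shallower of the TAFH-deleted clones. Against knockout they stood at -0.17 in wild-type clone 1 and -0.09 in TAFH-deleted clone 2, both deeper. In TAFH-deleted clone 1, which was shallower than knockout, they stood at 0.02. An even filling of positions, corrected gene by gene, does not explain it, since the median was 0.16 before and 0.19 after the correction.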

How the results depend on the processing

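Comparisons are knockout against control (A), wild-type rescue against knockout (B), TAFH-deleted rescue against knockout (C), TAFH-deleted against wild-type rescue (D) and wild-type rescue against control (E), with counts as higher and lower. D moved from 112 and 203 to 36 and 106 with pseudocount 0.1, 19 and 46 at a mean of at least 5 FPKM, 52 and 123 after quantile normalization, 44 higher after median scaling, 66 higher with robust eBayes, 17 higher with chromosomes centred, 45 higher when corrected for filled positions, and 9 and 81 without X and Y. Without a filter D gave 0 and 0, A 36 and 177, and E 14 and 250. At a threshold of 0.1, D gave 971 and 754 and E 33 lower, and with a log2 change of at least 1, D gave 62 higher. Fitted on the compared groups alone, B gave 1338 and 1831, D 74 higher, and E 759 and 2095. Among genes under 20% filled E gave 56 lower. With short transcripts kept, A gave 8 and 7, B 8 and 13, C 1 and 12, D 24 and 82, and E 4 and 29. TAFH dependence of knockout-lowered genes (called lower in A and D) was then 1. Rescue of knockout-lowered genes (called lower in A, higher in B) was 1. Rescue of knockout-lowered genes by the deleted form (called lower in A, higher in C) was 1. These 3 overlaps follow in that order. With all 8 libraries separate, A gave 1133 and 1724, B 1263 and 1735, C 497 and 577, D 2718 and 1848, E 604 and 1825, and the overlaps 593, 716 and 275. With short transcripts kept as well, these were 1088 and 1676, 1245 and 1718, 499 and 570, 2688 and 1853, 614 and 1771, and 590, 706 and 275. With a replicate block on 8 separate libraries they were 719 and 1300, 967 and 1265, 150 and 311, 2290 and 1631, 319 and 1303, and 459, 531 and 99. The overlap by size of knockout-lowered genes (at least 2-fold lower in A, called lower in D), 89, was 0 without a filter, 21 at a mean of at least 5 FPKM, 48 after quantile normalization, 269 with 8 separate libraries, 273 with short transcripts as well, 258 with the block, 47 without X and Y, and 43 with short transcripts kept. The median of D in the lowered genes, -0.30, was -0.58 with pseudocount 0.1. With an estimated correlation, a test that almost no list could pass here, 0 gene lists passed. Leaving out a library gave lowest and highest counts of 0 to 1001 higher and 0 to 1717 lower in A, 0 to 1316 and 0 to 1901 in B, 0 to 2136 and 0 to 1877 in C, 0 to 3854 and 0 to 2868 in D, and 0 to 778 and 0 to 2198 in E. The overlaps ran from 0 to 588, 0 to 649 and 0 to 848, and the overlap by size from 0 to 312. All high counts came from leaving out a TAFH-deleted clone, since the spread then rests on the wild-type clones alone, and D fell to 0 without either wild-type clone. The balance of D turned from more lower to more higher with 8 separate libraries, with the block, without either TAFH-deleted clone, and at a threshold of 0.1. C without TAFH-deleted clone 1 also gave more higher than lower. The median of E-protein targets in A, -0.06, turned to 0.15 after quantile normalization. None of the 36 named genes called in D changed direction, but they were picked among genes called in the same libraries, so a reversal was unlikely. Of these 36, 0 stayed called without a filter, 16 with short transcripts kept, 21 with pseudocount 0.1 and 24 with chromosomes centred.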

Other observations

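The TAFH-deleted clones stood apart in several lists, a difference between 2 single clones that was not tested. Interferon-stimulated genes stood at medians of -0.27 in clone 1 and -1.07 in clone 2 against knockout, and unfolded protein and ATF4 response genes at -0.51 and -0.09. Ifitm1, an interferon-induced membrane protein, was at 18.3 and 0.261 FPKM in these clones, and 21.6 in knockout.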
